A study of Mus musculus with 13 samples.

How the data were processed

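Total RNA from 13 mouse cell samples was amplified, labelled with biotin and hybridised to Affymetrix Mouse Exon 1.0 ST arrays, which measure the abundance of most transcripts at once. The labels place the arrays in 7 lines: induced pluripotent stem (iPS) clones 1, 2, 5 and 6, embryonic fibroblasts (MEF), embryonic stem (ES) cells named MPSVII, and the ES line B6 Blu. Each line has 2 arrays except B6 Blu ES, which has 1. Per the labels, the clones were made with a lentivirus carrying the factors abbreviated OSK (Oct4, Sox2 and Klf4). The label texts differ on one point: the titles and the design text name fibroblasts of the disease model MPSVII, while the source and growth fields of the clones and fibroblasts name wildtype B6 embryos. The names in the titles are used here, and no label states the sex of any line or whether the replicates of a line came from separate cultures. The series title speaks of genome sequencing, but the values are array expression values.

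The deposited table holds log2 signal that the authors made with Affymetrix Expression Console and the RMA method, whose versions are not given. RMA corrects for background, makes the probe distributions of the arrays alike and summarises probes by median polish. The summarised values of the arrays still differed in spread. Their medians lay between 3.97 and 4.45, and their interquartile ranges between 1.70 and 2.83, with the narrowest on the arrays of clone 2 and the widest on those of MEF. Signal files, detection calls and single probes were not used here.

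The table has 23238 rows. A range of low row numbers with 6577 rows carries no gene in the annotation of the array, against 95.6% of the other rows with a gene, and was left out as array controls. The plan made before the data were examined was to leave out control rows, but which rows these were was identified after the table was seen and before any test was run. The remaining 16661 rows were tested. Of these, 14939 carry 1 gene symbol, 989 several and 733 none. By Entrez number, 14884 of the single-gene rows were matched to the RefSeq genes of the mouse assembly GRCm38.p6, used for names and chromosomes, and 0 symbols changed. The single-gene rows hold 14807 distinct symbols, 131 of them on more than 1 row.

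Differences between lines were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per line was fitted to all 13 arrays (lmFit, then eBayes without trend), which gave 6 residual and 4.53 prior degrees of freedom and a median residual SD of 0.252 log2 units. The comparisons were the mean of the 4 clones, each weighted equally, minus MEF and minus MPSVII ES, MPSVII ES minus MEF, MPSVII ES minus B6 Blu ES, each clone minus MPSVII ES, and differences among the 4 clones by limma's moderated F test. A row was called when its Benjamini-Hochberg adjusted p lay under 0.05 over all rows of a comparison. Errors after ± are the standard errors of limma. B6 Blu ES has a single array, so its spread was assumed to be that of the other lines.

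Gene lists for 24 cell types and pathways were written before the data were examined. They name 545 genes, of which 434 were matched to a row, with the row of highest mean taken where a gene had several. Each list was tested in 4 comparisons with limma's camera at a preset correlation of 0.01, adjusted over all 96 tests, and again with a correlation estimated from the arrays and with fry. Lists of rows at least 2 log2 units higher (MEF-high) or lower (ES-high) in MEF than on the B6 Blu ES array were tested with camera in the clones minus MPSVII ES. The genes named were fixed by a rule: the 10 largest increases and decreases among called single-gene rows whose arrays on both sides do not overlap, 5 each way for single clones, 10 by range among clones, up to 4 members of each list, the reprogramming factors, the imprinted genes of the Dlk1 to Dio3 region, the sex-linked list, Gusb and Nnt. Comparisons, tests and the naming rule were chosen before the data were examined.

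The alternatives planned were a replicate block, leaving out each of 12 arrays in turn, leaving out dim rows, quantile normalization, centring each array on its median, a trended and robust variance prior, fitting the compared lines alone, array weights, line means as samples, a minimum log2 difference of 1, and rows with 1 symbol. Chosen after seeing the data were all rows of the table, an intensity-dependent (loess, span 0.3) normalization, leaving out clone 2, and clone means as samples. On simulated data with the same layout and 200 changed rows among 16661, 100 of each size, the model recovered 50% of changes of 1 log2 unit and 95% of changes of 2 for the clones minus MPSVII ES, with 5 false calls. For MPSVII ES minus MEF these shares were 27% and 74%, with 9 false calls among 110. For MPSVII ES minus B6 Blu ES they were 9% and 59%, with 2 false calls among 70. The simulated noise was independent between rows, without shifts of whole arrays or other differences between clones. False calls on the real arrays may therefore be more frequent. The number of arrays limits the precision of every value. Leaving out 1 array of a line with 2 leaves 1 there and fewer residual degrees of freedom. Such a fit has less power, so a lost call or a lower count need not mark that array. The p-values measure the spread between these arrays alone, which may be technical.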

Results

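Expression was measured in 13 arrays of mouse cells: 8 arrays of 4 iPS clones (1, 2, 5 and 6, with 2 arrays each), 2 arrays of MEF, 2 of MPSVII ES and 1 of B6 Blu ES. MPSVII is mucopolysaccharidosis type VII, a lysosomal storage disease caused by loss of the enzyme beta-glucuronidase, which Gusb encodes. iPS cells are body cells returned to a state like that of ES cells by added transcription factors. Values are log2 signal, and the arrays of a line correlated across rows with r between 0.955 and 0.982. Rows are not independent replicates, and r describes likeness of profiles alone. Between clones and MPSVII ES r lay between 0.941 and 0.976, with the lowest values for clone 2 (0.941 to 0.951), and between clones and MEF from 0.802 to 0.847.

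The targeted gene and the reprogramming factors were followed array by array. Gusb, the gene affected in MPSVII, gave low signal throughout: 3.47 to 4.25 in the 8 clone arrays, 3.76 and 3.72 in MPSVII ES, 5.07 and 3.98 in MEF and 4.50 in B6 Blu ES. It did not differ between MPSVII ES and B6 Blu ES beyond the spread (log2 difference -0.76 ± 0.38, adjusted p = 0.571). Its difference between the clones and MEF, -0.79 ± 0.24 (adjusted p = 0.0267), rested on 1 MEF array. Without MEF replicate 1 it was -0.24, and it did not pass the test after quantile normalization (-0.45), median centring (-0.52) or the intensity-dependent normalization (-0.63). Pou5f1, which encodes Oct4, rose by 2.69 ± 0.19 from MEF to the clones (adjusted p = 1.41e-06) and Sox2 by 3.44 ± 0.17 (adjusted p = 1.19e-07). Klf4 did not pass the test in any of the 4 main comparisons, with -0.39 ± 0.26 in the clones minus MEF (adjusted p = 0.309; -0.54 and past the test without clone 2 replicate 1). Myc, which the label of the virus does not name, fell between MEF, at 6.47 and 5.93, and the 8 clone arrays, at 4.10 to 5.10 (adjusted p = 9.61e-05). Nnt, a mitochondrial transhydrogenase known to differ between B6 substrains, was not called in any of the 4 main comparisons. It differed by -0.70 between the clones and MPSVII ES (adjusted p = 0.148). Its signal was 4.78 and 4.42 on the arrays of clone 2, against 5.55 and 5.90 in MPSVII ES.

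**Figure D1:**
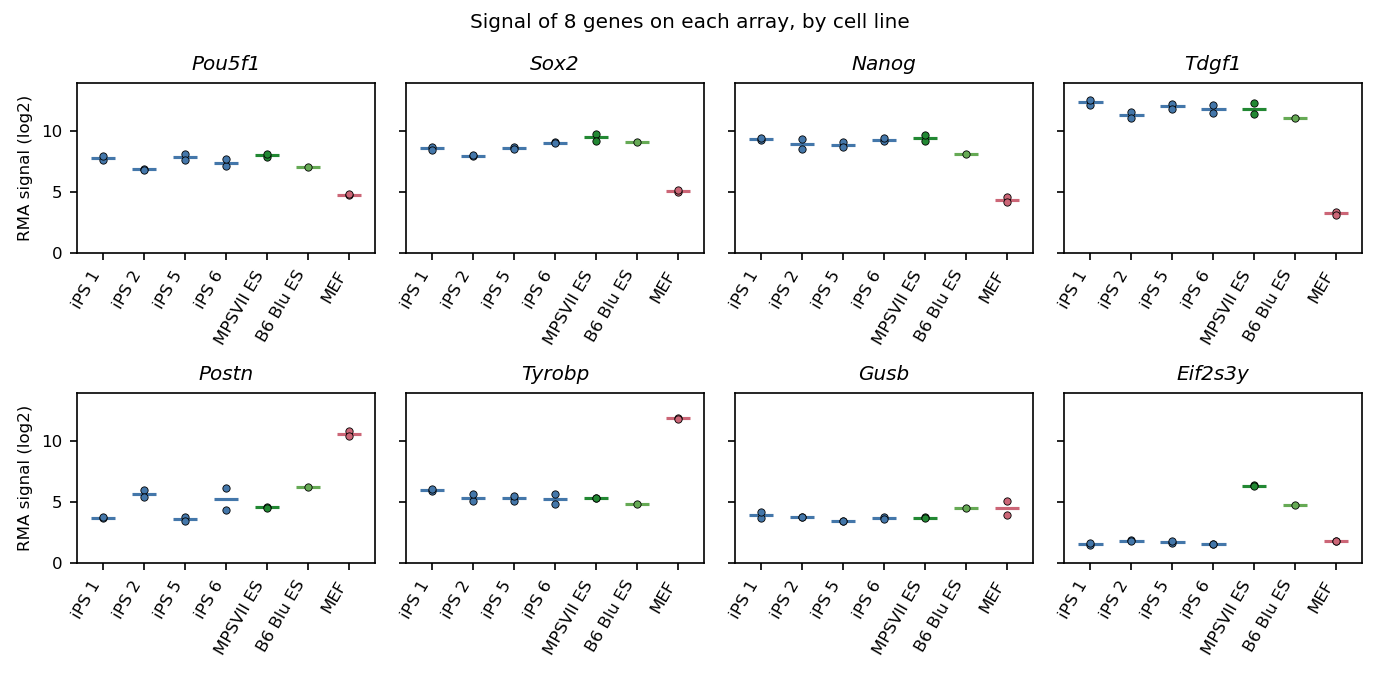
RMA signal (log2, y axis) of 8 genes on each of the 13 arrays by cell line (x axis), with points for arrays and bars for line means. Eif2s3y lies at 6.41 and 6.31 in MPSVII ES, at 4.80 in B6 Blu ES and between 1.52 and 1.91 in all clone and MEF arrays, while Gusb stays between 3.47 and 5.07.

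The clones minus MEF comparison asks how far the fibroblast programme was replaced. Most members of the pluripotency list rose, and most members of the fibroblast, lysosome and macrophage lists fell in the clones. The largest increases were Tdgf1, a co-receptor of Nodal signalling, by 8.62 ± 0.27, Cyct, a testis cytochrome c, by 7.35 ± 0.18, and Spink1, a trypsin inhibitor, by 7.27 ± 0.22. Dppa4 and Sall4, nuclear factors of early embryonic cells, rose by 6.61 and 6.13, the epithelial adhesion molecule Epcam by 5.64 and Nanog by 4.73. Among the largest decreases were genes of myeloid cells, Lcp1 at -6.59, Tyrobp at -6.41, C3ar1 at -6.22 and the macrophage elastase Mmp12 at -6.09. Matrix genes among them were Mgp at -6.39, Efemp1 at -6.33, the collagen gene Col12a1 at -6.04 and Postn at -6.04. The rule for naming the largest increases and decreases required that the arrays of both sides not overlap.

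By list, 27 of 31 pluripotency genes rose and 0 fell in the clones against MEF (28 and 0 adjusted over the list alone), with a median of 2.12 (camera adjusted p = 1.66e-22; adjusted p = 0.074 with an estimated correlation). Tdgf1, Dppa4, Sall4 and Nanog had the largest increases of the list. Of 37 fibroblast and matrix genes 35 fell and 0 rose (36 and 0 adjusted over the list alone; median -2.70, camera adjusted p = 5.86e-17; adjusted p = 0.262 with an estimated correlation), among them Acta2, smooth muscle actin, at -5.34, the mesenchymal regulator Prrx1 at -5.25 and the matrix gene Thbs1 at -5.21. In the epithelial list 11 of 22 genes rose and 1 fell (13 and 1 adjusted over the list alone; median 0.60, camera adjusted p = 6.73e-07; adjusted p = 0.266 with an estimated correlation), including E-cadherin (Cdh1) by 2.18 and the splicing factor Esrp1 by 1.94. The member that fell was Perp, a component of desmosomes, at -1.30, chosen after its values were seen, whose call was lost after quantile normalization (-0.58). Of 4 reprogramming factors 2 rose and 1 fell, with the same counts adjusted over the list alone. This list did not pass camera (adjusted p = 0.139) but passed fry (adjusted p = 0.000115).

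Markers of another cell type were high on the MEF arrays. Of 14 blood and macrophage markers 13 were lower in the clones than in MEF and 0 higher, with the same counts adjusted over the list alone and a median of -3.89 (camera adjusted p = 6.23e-11; adjusted p = 0.0623 with an estimated correlation). Among them were the Fc receptor chain Fcer1g at -5.34, the mannose receptor Mrc1 at -5.32 and Adgre1, the F4/80 antigen, at -5.24. The lysosome list moved with these markers: 34 of its 39 genes fell and 0 rose (35 and 0 adjusted over the list alone; median -2.08, camera adjusted p = 7.86e-14; adjusted p = 0.272 with an estimated correlation). Lipa, the lysosomal acid lipase, stood at -5.31, the cathepsins Ctsd and Ctsb at -4.57 and -4.55, and the saposin precursor Psap at -3.89. After quantile normalization 31 lysosome genes were lower and 1 higher.

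The cell cycle, germ cell, chromatin and p53 lists passed camera in the clones minus MEF with the preset correlation, and none of them with an estimated one. All of them passed fry (adjusted p = 0.000705, 0.000103, 0.000575 and 4.44e-05), as did the pluripotency, fibroblast, epithelial, macrophage and lysosome lists. The glycolysis list did not (fry adjusted p = 0.309). In the cell cycle list 24 of 27 genes rose and 0 fell, with the same counts adjusted over the list alone (median 1.56, camera adjusted p = 4.25e-17; adjusted p = 0.262 with an estimated correlation), such as the spindle checkpoint kinase Bub1 by 2.81 and the mitotic kinesin Kif11 by 2.55. Of 16 germ cell genes 11 rose and 0 fell (12 and 0 adjusted over the list alone; median 1.24, camera adjusted p = 1.89e-10; adjusted p = 0.197 with an estimated correlation), with the meiotic genes Hormad1 by 4.31 and Smc1b by 3.24 and the helicase Ddx4 by 2.58. In the list of DNA methylation and chromatin genes 12 of 21 rose, 2 fell and 7 were not called (13 and 2 adjusted over the list alone; median 1.24, camera adjusted p = 1.92e-09; adjusted p = 0.286 with an estimated correlation), including Dnmt3l by 3.14, Mtf2 by 2.89 and Jarid2 by 2.77. After quantile normalization, median centring and the intensity-dependent normalization 17 of these rose and 0 fell. The p53 and senescence list had 16 of 19 genes lower and 0 higher, with the same counts adjusted over the list alone (median -1.30, camera adjusted p = 4.54e-06; adjusted p = 0.247 with an estimated correlation), among them Igfbp7 at -4.12, the death receptor Fas at -3.82 and the cell cycle inhibitor Cdkn1a at -3.28. After quantile normalization 10 of these were lower and 2 higher. Of 16 glycolysis genes 3 rose and 1 fell, with the same counts adjusted over the list alone (median 0.32, camera adjusted p = 0.0365; adjusted p = 0.688 with an estimated correlation), led by the glucose transporter Slc2a3 at 3.89. The glycolysis list did not pass camera without clone 2 replicate 1 (median 0.15), clone 6 replicate 2 (median 0.25) or MEF replicate 2 (median 0.17), nor after median centring.

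In all, 5803 of 16661 rows (34.8%) were called between the clones and MEF, 1297 higher and 4506 lower in the clones, and 3565 of them differed by at least 1 log2 unit. The share of higher rows, 22.4%, depended on the scaling: 3333 rows were higher and 3113 lower after quantile normalization, 3472 and 3613 after median centring, and 2799 and 3837 after the intensity-dependent normalization. The median of all rows, -0.09 in the deposited values, was 0.11 and 0.17 after the former pair of scalings, so a small difference in either direction has no fixed sign.

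**Figure D2:**
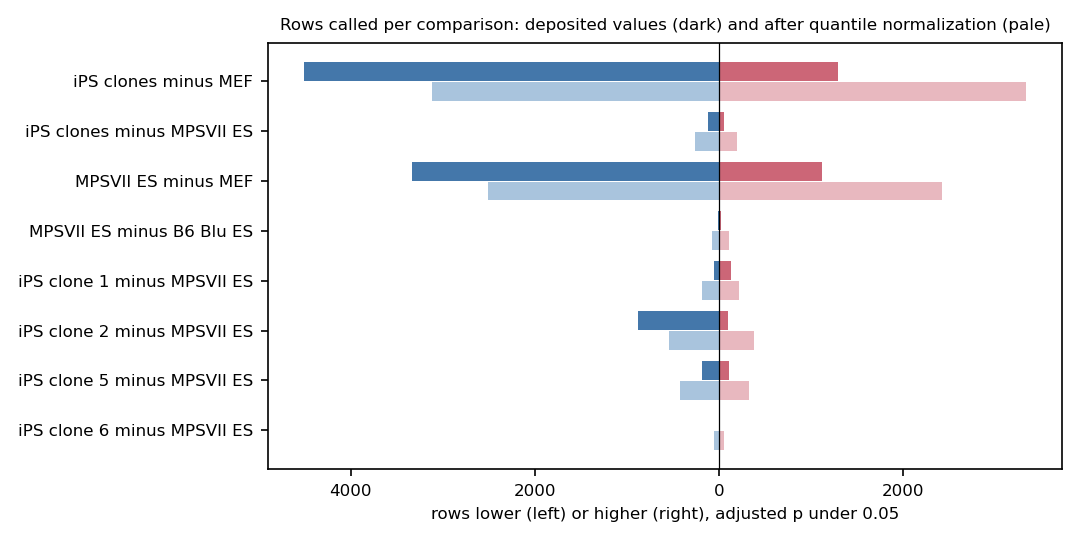
Number of rows called lower (left) and higher (right) with adjusted p under 0.05 in each comparison (y axis), from the deposited values (dark bars) and after quantile normalization (pale bars). In iPS clones minus MEF, 1297 higher and 4506 lower rows become 3333 and 3113.

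MPSVII ES minus MEF gives the size of the difference between ES cells and fibroblasts against which the clones are set. Tdgf1 was higher in ES cells by 8.56 ± 0.34, Cyct by 7.98 ± 0.22, Dppa4 by 6.64 ± 0.38 and Nanog by 5.06 ± 0.28. Acta2 stood at -7.62 ± 0.40, the matrix gene Efemp1 at -7.02 ± 0.27, the growth factor Ptn at -6.87, Mgp at -6.86, Tyrobp at -6.54 and the macrophage elastase Mmp12 at -6.16. Of the same lists, pluripotency had 27 of 31 genes higher and 0 lower (29 and 0 adjusted over the list alone; median 2.60, camera adjusted p = 6.37e-27; adjusted p = 0.0623 with an estimated correlation), fibroblast and matrix 35 of 37 lower and 0 higher (36 and 0 adjusted over the list alone; median -2.81, camera adjusted p = 3.5e-19; adjusted p = 0.262 with an estimated correlation), and blood and macrophage 13 of 14 lower and 0 higher (median -3.88, camera adjusted p = 1.94e-12; adjusted p = 0.0623 with an estimated correlation). In the lysosome list 29 of 39 were lower and 1 higher (32 and 1 adjusted over the list alone; median -1.76, camera adjusted p = 9.75e-12; adjusted p = 0.292 with an estimated correlation). Cell cycle genes were higher in 25 of 27 cases and lower in 0 (median 1.59, camera adjusted p = 1.21e-17; adjusted p = 0.262 with an estimated correlation). The comparison called 4452 rows, 1117 higher and 3335 lower. After quantile normalization 2418 were higher and 2503 lower, after median centring 2043 and 2866, and after the intensity-dependent normalization 2010 and 3160, with the median of all rows moving from -0.08 to 0.09 and 0.13 under the former pair.

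The differences of the clones from MEF and of MPSVII ES from MEF had many rows in common. Called higher in both were 866 rows and lower in both 3189, against 87.0 and 902 for lists drawn independently, and 1 row was called in opposite directions. The log2 differences correlated across rows with r = 0.946. Both comparisons subtract the same MEF arrays, and 20 simulations without any effect gave a mean r of 0.631 and 0 shared calls. An r from noise alone is not on the scale of an r from data with large differences. The covariance of the log2 differences was 0.995, against a mean of 0.0493 in these simulations. Independent noise of the shared arrays, as simulated, therefore gave a small part of it. The simulations held no shift of whole arrays and nothing particular to the MEF arrays, such as their wider range or macrophage markers. How much of the covariance these gave was not tested. Of the 173 rows called between the clones and MPSVII ES, 120 (69.4%) were among the 4452 that differed between MPSVII ES and MEF, against 46.2 for lists drawn independently. Both comparisons use the MPSVII ES arrays. In 20 simulations with the clones at the level of MPSVII ES, as many rows of lowest p shared a mean of 95.8 and at most 108.

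The clones minus MPSVII ES comparison, the one the design text names, asks how the reprogrammed cells differ from ES cells of the embryo. The Y-linked translation factor gene Eif2s3y was lower in the clones, at -4.66 ± 0.13 (adjusted p = 4.7e-08, no overlap between 8 and 2 arrays), and it was equally low in MEF. Spink1, the trypsin inhibitor, was higher by 3.34 ± 0.22 (adjusted p = 7.45e-05) and the oocyte homeobox gene Obox6 by 2.62 ± 0.22 (adjusted p = 0.000871). The X-linked gene Efhc2 was higher by 2.31 ± 0.23 and the X-linked zinc finger gene Zfp280c by 1.78 ± 0.17. These 5 passed the test in each of the 12 fits that left out 1 array. With clone means as samples Eif2s3y passed (adjusted p = 0.0127) and Spink1, Obox6, Efhc2 and Zfp280c did not (adjusted p = 0.999). Further increases were Acta2 at 2.28, the protease Mep1b at 1.85, the fatty acid desaturase Scd1 at 1.76 and carbonic anhydrase Car2 at 1.45, and further decreases Erc1 at -2.51, the matrix protease Mmp3 at -2.35, the chloride channel subunit Lrrc8d at -2.09, the cysteine dioxygenase Cdo1 at -1.96 and the matrix gene Dcn at -1.71. Of these, Erc1 lost its call in 8 of the 12 fits and the others in 1 or 2.

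In the clones minus MPSVII ES 4 of 31 pluripotency genes fell, 0 rose and 27 were not called over all rows (17 lower and 1 higher adjusted over the list alone), with a median of -0.54 (camera adjusted p = 1.38e-09; adjusted p = 0.234 with an estimated correlation), and the median was -0.46 to -0.49 under the other scalings. The 4 were Mybl2 at -1.25, a regulator of the cell cycle, Utf1 at -1.17, Tfcp2l1 at -0.99 and Sox2 at -0.94, and their calls were lost in 9, 3, 10 and 7 of the 12 fits that left out 1 array. Pou5f1 at -0.53 (adjusted p = 0.274) and Nanog, chosen after its values were seen, at -0.33 (adjusted p = 0.637) did not pass. Myc fell by 1.00 ± 0.19 (adjusted p = 0.0422, lost in 8 of 12 fits), and of 4 reprogramming factors 2 fell (3 adjusted over the list alone; camera adjusted p = 0.000867; adjusted p = 0.119 with an estimated correlation). Of 16 germ cell genes 2 fell, Ddx4 at -1.46 and the synaptonemal gene Sycp3 at -1.14 (5 lower and 1 higher adjusted over the list alone; median -0.22, camera adjusted p = 0.0251; adjusted p = 0.637 with an estimated correlation), and this list did not pass without clone 2 replicate 1 (median -0.22), clone 6 replicate 1 (median -0.17) or MPSVII ES replicate 1 (median -0.05). Sycp3 lost its call in 11 of the 12 fits that left out 1 array (-0.72 without MPSVII ES replicate 1) and Ddx4 in 1. Sycp3 stood at 3.41 in clone 2, between 6.06 and 6.64 in the other clones and at 6.69 in MPSVII ES. In MPSVII ES minus B6 Blu ES the pluripotency and germ cell lists had medians of 0.79 and 1.29. The single B6 Blu ES array thus also lay below MPSVII ES in both lists. That array also had higher fibroblast and matrix genes (median -0.48 in MPSVII ES minus B6 Blu ES). It therefore does not settle whether ES lines share the shifts of the clones. Both comparisons use the MPSVII ES arrays. Both sex-linked genes of the list matched to rows, Eif2s3y and the Y-linked demethylase gene Kdm5d (-1.40; call lost without MPSVII ES replicate 1), fell (camera adjusted p = 6.38e-10; adjusted p = 0.0614 with an estimated correlation).

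The lysosome list had a median of -0.29 and passed camera with the preset correlation (camera adjusted p = 0.000102), but not with an estimated correlation (adjusted p = 0.619) or by fry (adjusted p = 0.213). Over all rows 1 of 39 fell, the beta-mannosidase Manba at -1.13, whose call was lost in all 12 fits that left out 1 array. Adjusted over the list alone 8 fell and 1 rose. In MPSVII ES minus B6 Blu ES the lysosome list had a median of 0.33, so the B6 Blu ES array also lay below MPSVII ES. Fibroblast and matrix genes did not shift as a list (1 higher, Acta2, and 1 lower, Dcn, of 37; 2 and 1 adjusted over the list alone; median 0.05, camera adjusted p = 0.223). The imprinted genes Dlk1, Rtl1 and Dio3 differed by 0.13, -0.14 and 0.07 (adjusted p = 0.842, 0.842 and 0.961). Of the 6 genes written for this region only these 3 were matched to a row. Rtl1 and Dio3 stayed between 2.44 and 3.51 on all arrays, so these values do not settle whether genes of the region were silenced. No member passed in the p53 and senescence, chromatin, interferon or primed epiblast lists over all rows by limma. Adjusted over the list alone, 2 of 19 p53 and senescence genes were higher, 5 of 21 chromatin genes lower and 0 members passed in the others. Camera called each of these lists, with medians of 0.17, -0.25, 0.12 and 0.08 (adjusted p = 0.00279, 0.0153, 0.0329 and 0.0453). Each of these calls was lost with an estimated correlation (adjusted p = 0.372, 0.688, 0.526 and 0.603 with an estimated correlation), and that of p53 and senescence without MPSVII ES replicate 2 (median 0.10), that of interferon in 3 and that of primed epiblast in 5 of 12 fits that left out 1 array.

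In all, 173 rows (1.04%) were called between the clones and MPSVII ES, 53 higher and 120 lower, and 2018 rows lay at an unadjusted p under 0.05. Leaving out 1 array also lowers the power, so a lower count does not single out that array. The count depended on the ES arrays and on single clones: it was 6 without MPSVII ES replicate 1, 33 without MPSVII ES replicate 2, 97 and 85 without clone 1 replicate 1 and 2, 103 without clone 5 replicate 2 and 103 without clone 6 replicate 1. It was 192 higher and 263 lower after quantile normalization, 121 and 188 after median centring, 186 and 229 after the intensity-dependent normalization, 114 with a replicate block, and, with clone means as samples, 0 higher and 2 lower (702 at an unadjusted p under 0.05). Without clone 2 it was 198, of which 117 were among the 173, and the split turned to 116 higher and 82 lower.

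Whether fibroblast-high genes stayed higher and ES-high genes lower in the clones was examined with rows chosen on arrays outside this comparison. The 959 rows that were at least 2 log2 units higher in MEF than in B6 Blu ES had a median of -0.06 in the clones minus MPSVII ES (camera adjusted p = 0.481), and the 122 rows at least as much lower in MEF also had -0.06 (camera adjusted p = 0.326). Among single clones, ES-high rows were lower in clone 2, with a median of -0.59, 35 rows lower and 4 higher (camera adjusted p = 2.27e-07; adjusted p = 0.888 with an estimated correlation). Random lists matched on mean expression had a median of -0.40 in the same clone, and the ES-high median was -0.16 after the intensity-dependent normalization. The median of the ES-high rows was 0.30 in clone 1 (camera adjusted p = 0.174), -0.08 in clone 5 (camera adjusted p = 0.481) and 0.14 in clone 6 (camera adjusted p = 0.183). After the intensity-dependent normalization clone 1 had 0.06, under the 95th percentile of random lists (0.08), clone 5 had -0.06, above the 5th percentile (-0.07), and clone 6 had 0.11, above the 95th percentile (0.06). In the deposited values clones 1 and 6 lay above the 95th percentile (0.22 and 0.09) and clone 5 below the 5th (-0.06). Single arrays moved these medians. That of clone 1 was 0.11 without its replicate 2 and 0.42 without its replicate 1, and it passed camera without that array and without MEF replicate 2 (adjusted p = 0.0176 and 0.0465). That of clone 6 was -0.04 without its replicate 2 and 0.30 without its replicate 1, where it passed (adjusted p = 0.00376). That of clone 5 was -0.19 without its replicate 1, 0.11 without its replicate 2 and 0.03 without MPSVII ES replicate 2, and it did not pass.

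The minimum difference that defines the lists was also set to 1 and 3 log2 units, and no list passed camera there with an estimated correlation (adjusted p between 0.559 and 0.995 in the deposited values). With the preset correlation the ES-high rows of clone 1 passed (medians 0.11 and 0.37, adjusted p = 0.0424 and 0.0159), those of clone 2 too (medians -0.38 and -0.51, adjusted p = 0.00451 and 0.0159), and at 3 units those of clone 6 (median 0.33, adjusted p = 2.47e-06). The median of clone 2 at 3 units lay within the range of random lists, whose 5th percentile was -0.57. After the intensity-dependent normalization the ES-high calls of clones 1 and 2 were lost (camera adjusted p between 0.498 and 0.724). That of clone 6 at 3 units was kept (median 0.26, camera adjusted p = 0.00313). At 1 unit the MEF-high rows of clone 2 had a median of -0.32 (adjusted p = 0.000435) where random lists had -0.22, and after the intensity-dependent normalization they had -0.04 and did not pass camera (adjusted p = 0.498).

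Single clones were compared with MPSVII ES because the design text sets the separate clones against these cells. Spink1 was higher in clone 1 by 3.40 ± 0.27, in clone 2 by 4.29 ± 0.27 and in clone 5 by 3.79 ± 0.27. Obox6 was higher by 3.20, 3.65 and 2.89 in the same clones, and Efhc2 by 3.89 in clone 2 and 3.15 in clone 5. In clone 2 the preimplantation gene Pramel7 was higher by 2.92 and the histone mRNA binding protein gene Slbp stood at -3.94, Sycp3 at -3.28 and the coactivator gene Edf1 at -2.99. Clone 5 had the histone gene H2bu2 higher by 3.79 and the tubulin cofactor gene Tbcc at -3.08. Of the 12 fits that left out 1 array, 4 ended the call of H2bu2, 2 that of Tbcc and 1 each that of Slbp and Edf1 in these clones. Clone 6 had Mep1b higher by 2.35, Duxbl1, a homeobox gene, by 1.95 and the lysosomal membrane gene Laptm5 at -1.40. These calls were lost in 11, 11 and 10 of the 12 fits. Eif2s3y was lower in every clone, between -4.79 and -4.49. Called in all 4 clones in the same direction were 4 rows. Higher was the X-linked Zfp280c, by 1.08 to 2.32. Lower were the Y-linked Kdm5d and Eif2s3y and a row without a single gene name. These 4 were chosen after their values were seen. Zfp280c in clone 6 lost its call in 10 of the 12 fits that left out 1 array and Kdm5d in 6. Pou5f1 in clone 2 stood at -1.15 ± 0.25 (adjusted p = 0.0253), and at -0.63 without passing the test after the intensity-dependent normalization. Its call was lost in 4 of 12 fits.

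The number of called rows was 180 in clone 1 (126 higher, 54 lower), 983 in clone 2 (100 higher, 883 lower), 296 in clone 5 (110 higher, 186 lower) and 8 in clone 6 (4 higher, 4 lower). Clone 6 had 1358 rows at an unadjusted p under 0.05. Whether these counts differ between clones was not tested. After quantile normalization the splits were 216 and 181, 382 and 545, 325 and 420, and 58 and 54 for clones 1, 2, 5 and 6, after median centring 289 and 93, 177 and 973, 217 and 263, and 27 and 19, and after the intensity-dependent normalization 268 and 201, 208 and 262, 301 and 406, and 53 and 45. The counts changed when single arrays were left out, which also lowers the power, so a lower count does not single out that array. Clone 1 had 31 and 7 without its replicates 1 and 2, 119 without either array of clone 6, and 7 and 18 without MPSVII ES replicates 1 and 2. Clone 2 had 197 without its replicate 2 and 32 and 158 without MPSVII ES replicates 1 and 2. Clone 5 had 101 and 13 without its replicates, 197 without either array of clone 1, and 18 and 45 without MPSVII ES replicates 1 and 2. Clone 6 had 2 without its replicate 2, without either array of clone 1 or without either of MPSVII ES, and 5 without either of clone 5.

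Differences among the clones were tested directly with the F test. The widest range of clone means was that of Slbp, which stood at 7.13, 2.82, 7.15 and 6.93 in clones 1, 2, 5 and 6 (range 4.34, adjusted p = 0.00454). Pramel7 was highest in clone 2, at 7.69 against 3.63 to 5.00. Txnip, an inhibitor of thioredoxin, stood at 5.88 in clone 2 and 9.68 in clone 1. Emb, a membrane glycoprotein gene, stood at 4.25 in clone 2 and at 7.79 or above in the others, and Edf1 at 5.86 and 6.28 in clones 2 and 6 and 8.85 and 9.65 in clones 1 and 5. Among list members, 9 of 27 cell cycle genes, 7 of 31 pluripotency genes, 7 of 16 germ cell genes, 7 of 21 chromatin genes and 5 of 22 epithelial genes differed among clones. In all, 1501 rows (9.01%) differed, 1379 of them with a range of at least 1 log2 unit. The count was 134 without clone 2, 674 without clone 1 replicate 2 and 487 without clone 2 replicate 2.

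**Figure D3:**
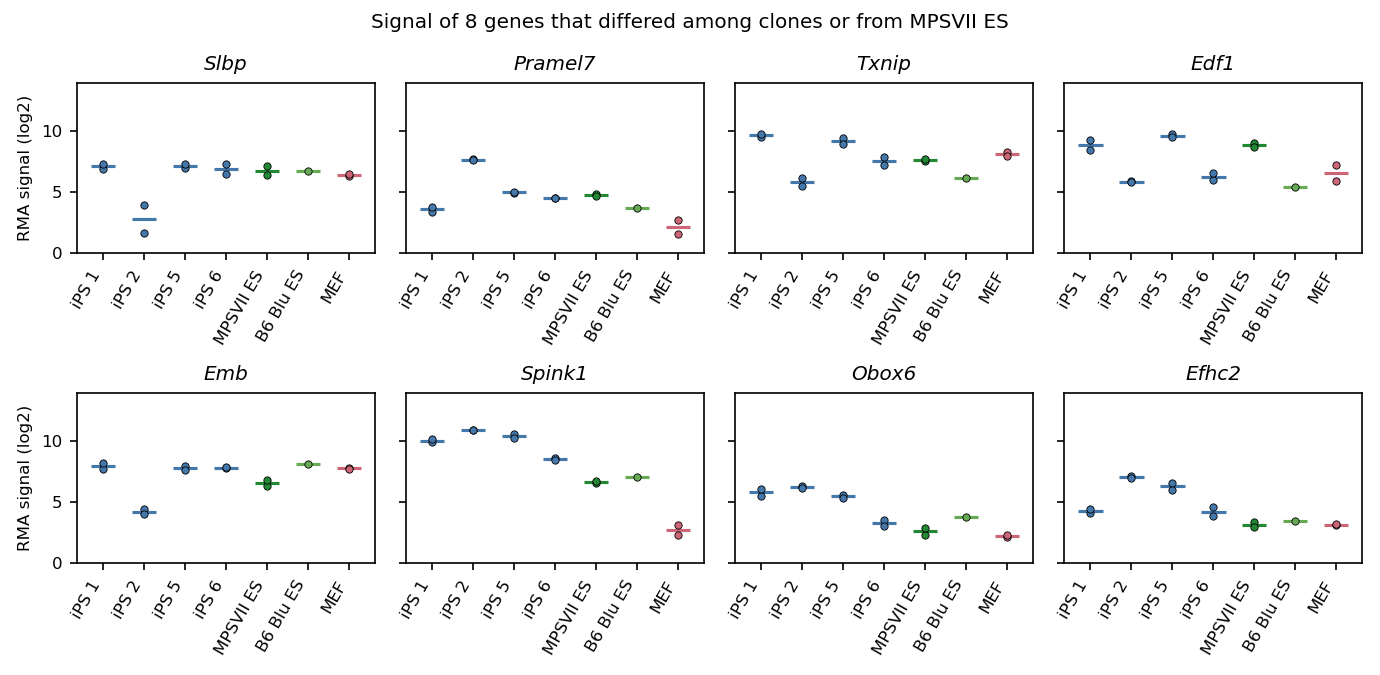
RMA signal (log2, y axis) of 8 genes on each of the 13 arrays by cell line (x axis), with points for arrays and bars for line means. Slbp and Emb are lowest in clone 2 (means 2.82 and 4.25), and Pramel7 is highest there (7.69).

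MPSVII ES minus B6 Blu ES sets the ES cells of the disease model against a control ES line with another strain label. Of the germ cell genes, 3 of 16 were called, all higher in MPSVII ES: the meiotic cohesin gene Smc1b by 2.89 ± 0.35, Sycp3 by 2.25 ± 0.35 and Ddx4 by 1.87 ± 0.26. The X-linked testis genes Fmr1nb and Usp26 were higher by 3.86 ± 0.30 and 3.12 ± 0.24, Edf1 by 3.44 ± 0.50 and Cyct by 2.85 ± 0.27. Higher on the single B6 Blu ES array were Acta2 at -4.78 ± 0.49, the fibroblast marker S100a4 at -4.00 ± 0.62, calponin (Cnn1) at -3.04 ± 0.33, the tropomyosins Tpm2 and Tpm1 at -2.70 and -2.63, the surface marker Thy1 at -2.67 and Prrx1 at -2.18. Leaving out 1 array ended the call of Sycp3 in 9 of 12 fits, of S100a4 and Tpm1 in 8, of Prrx1 in 4, of Ddx4, Edf1 and Thy1 in 2 and of Smc1b, Cnn1 and Tpm2 in 1. The calls rest on a spread taken from other lines, since B6 Blu ES has 1 array. With the compared lines alone 6 rows passed in place of 34, among them Fmr1nb, Usp26, Edf1, Acta2 and Cnn1, while Smc1b, Ddx4 and Sycp3 did not (adjusted p = 0.0654, 0.0911 and 0.12).

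Of 16 germ cell genes 3 were higher and 0 lower (9 and 0 adjusted over the list alone; median 1.29, camera adjusted p = 8.92e-11; adjusted p = 0.197 with an estimated correlation). Of 37 fibroblast and matrix genes 5 were lower in MPSVII ES and 0 higher (11 and 1 adjusted over the list alone; median -0.48, camera adjusted p = 2.04e-14; adjusted p = 0.286 with an estimated correlation). Of 11 muscle genes 0 were called over all rows by limma (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.31). By limma 0 pluripotency genes passed over all rows (8 higher adjusted over the list alone; median 0.79, camera adjusted p = 6.14e-10; adjusted p = 0.232 with an estimated correlation). Primed epiblast genes had a median of -0.49 (0 called over all rows, 1 lower adjusted over the list alone; camera adjusted p = 2.58e-05; adjusted p = 0.262 with an estimated correlation). The comparison called 34 rows, 22 higher and 12 lower in MPSVII ES, with 1572 at an unadjusted p under 0.05. It called 6 without MPSVII ES replicate 1, 10 without replicate 2, and after quantile normalization 109 higher and 77 lower.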

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

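Chosen after the result was seen were the random lists for ES-high rows at 3 log2 units, the test on chromosome 7, the random lists for the medians over segments, the count of called rows after the intensity-dependent normalization and that normalization itself. The other tests were written down before their results were seen. The search for single arrays far from the rest needs 4 arrays in a group and the count of other splits needs 3 in each, so neither applies to lines of 1 or 2 arrays.

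The genes below are listed because their differences from MPSVII ES differed between the clones by the F test, and they are the 10 with the widest range of clone means. Slbp, needed for the processing of histone mRNA, had a range of 4.34 log2 units (adjusted p = 0.00454), with 1.68 and 3.95 on the arrays of clone 2. Pramel7 had a range of 4.06, lowest in clone 1 and highest in clone 2. Txnip had a range of 3.81 (adjusted p = 0.00085). Edf1 had a range of 3.79, with clones 2 and 6 at 5.86 and 6.28, B6 Blu ES at 5.41 and MEF at 6.59. Emb had a range of 3.75 (adjusted p = 0.000307). Mnd1, a meiotic recombination gene, had a range of 3.30 (adjusted p = 0.0327), which became 2.80 and no longer passed after the intensity-dependent normalization (adjusted p = 0.0989). Its call was lost in 6 of the 12 fits that left out 1 array, with a range of 2.15 without clone 2 replicate 1 and 4.46 without clone 2 replicate 2. Krt18, an epithelial keratin, had a range of 3.28 and stood highest in clone 5 at 8.16. Sycp3 had a range of 3.23, with 3.41 in clone 2. Ivns1abp had a range of 3.22, with 5.62 in clone 2. H2bu2 had a range of 3.16, high in clones 1 and 5.

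The sex-linked genes form a pattern, in which the Y-linked genes Eif2s3y and Kdm5d were low in MEF and all clones, and 176 X-linked rows stood 0.642 and 0.345 log2 units above the autosomes in clones 2 and 5 minus MPSVII ES, against 0.129 and 0.0751 in clones 1 and 6, a difference between clones that was not tested itself. Clones 1 and 6 also lay above the 95th percentile of 10000 random lists (0.0782 and 0.0609), and MEF minus MPSVII ES gave 0.283, so a higher X is not particular to clones 2 and 5. Intensity-dependent differences are argued against by the lower value of clones 2 and 5 after that normalization, 0.323, against 0.0658 for the 95th percentile. The lowest of 8 medians over 4 segments of X in both clones was 0.303, so every segment was shifted, as more active X chromosomes than in MPSVII ES would give. The 99th percentile of random lists, -0.00498, lay below 0, and these lists hold unchanged rows. The comparison therefore cannot tell active X chromosomes from other causes that act along the whole chromosome. In the deposited values MEF came near clone 5 (0.283 against 0.345), so a shift of that size also arose outside the pluripotent lines. The 2 Y-linked genes differed on the B6 Blu ES array. Eif2s3y stood there at 4.80, but Kdm5d at 2.31, within the 1.94 to 2.43 of the clones and MEF. What stays open is the sex of the lines, which the labels do not state. Also open is whether low Y-linked signal reflects female origin or a lost Y chromosome, since Xist matched no row and DNA was not measured.

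Chromosome 11 stood out in MPSVII ES. Its 394 rows with a mean above 5 were higher there than in the 6 other lines by a median of 0.229 relative to other autosomes, against 0.0397 for the 99th percentile and 0.0814 for the highest of 10000 random lists. A bias of gene density as the whole source is argued against by the densest autosome, chromosome 7, at -0.0343, but the largest shift among the other dense autosomes, 0.0398 on chromosome 17, missed the bound of 0.0397 set beforehand, and with a minimum mean of 6 chromosome 17 stood at 0.148 beside 0.276 for chromosome 11, so a contribution of density stays open (with a minimum of 4, chromosome 11 stood at 0.121 and the next, chromosome 8, at 0.0249). A single array is argued against by the smaller shift of both MPSVII ES arrays, 0.196, and an intensity effect by the shift after the intensity-dependent normalization, 0.229. The lowest of 24 medians over 4 segments of the chromosome against each of 6 lines was 0.102, so every segment was shifted, as extra copies would give (all 24 share the MPSVII ES arrays). The 99th percentile of random lists, -0.0455, lay below 0, and these lists hold unchanged rows. The comparison therefore cannot tell extra copies from other causes that act along the whole chromosome. Extra copies of chromosome 11, a gain known from mouse ES cultures, may be present in these cells, a hypothesis that only DNA could settle.

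Clone 2 had the most rows lower than in MPSVII ES, and its arrays had the narrowest interquartile ranges (1.88 and 1.70), with rows of the highest signal class at a median of -0.48 against MPSVII ES, where the other clones lay between -0.06 and 0.10. After the intensity-dependent normalization clone 2 had 470 called rows in place of 983, of which 329 were shared, and clone 5 had 707, but after quantile normalization, which also equalises the range, clone 2 still led with 927 against 745, and after median centring, which does not, with 1150 against 480. The normalizations disagree, so whether a narrower signal range gave clone 2 its leading count cannot be told apart from a true difference. ES-high rows still had a median of -0.16 in clone 2 after the intensity-dependent normalization, below the 5th percentile of random lists (-0.0884), as lower ES-high genes would give. The random lists draw rows independently, while listed genes can vary together. Camera passed there with the preset correlation (adjusted p = 0.0101) but not with an estimated one (adjusted p = 0.981). Rows at least 3 log2 units lower in MEF had -0.12, above the 5th percentile of their random lists (-0.15). The amount of RNA amplified per array is not given in the labels, and neither explanation excludes the other.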

How the results depend on the processing

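Chosen after seeing the data were all rows of the table, the intensity-dependent normalization, leaving out clone 2 and clone means as samples. The cause was not tested where none is given.

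With arrays averaged, which leaves fewer samples, calls fell. Line means as samples, with both ES lines as 1 group, called 3211 rows in clones minus MEF, 2535 in MPSVII ES minus MEF and 0 in clones minus ES (limma, 874 at an unadjusted p under 0.05). Clone means as samples called 3060 against MEF and 2 against MPSVII ES. A minimum log2 difference of 1 left 3565 rows in clones minus MEF. The replicate numbers gave no pairing common to all lines: residuals correlated with r between -0.241 and 0.240 over 15 line pairs (median -0.0885, 4 over 0.1). Batches that join the arrays of some lines cannot be excluded by this check. With the replicate block, the counts were 114 in clones minus MPSVII ES and 114, 161 and 2 in clones 1, 5 and 6, and within 1.5 times elsewhere (5659 in clones minus MEF, 4266 in MPSVII ES minus MEF, 679 in clone 2, 1063 among clones).

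Counts against MPSVII ES rose under the other scalings except in clone 2, where 983 became 927 after quantile normalization, 1150 after median centring and 470 after the intensity-dependent normalization. After quantile normalization the others were 455 for all clones, 397, 745 and 112 for clones 1, 5 and 6 and 186 for MPSVII ES minus B6 Blu ES. After median centring they were 309, then 382, 480 and 46, and 87. After the intensity-dependent normalization they were 415, then 469, 470, 707 and 98 for clones 1, 2, 5 and 6, and 104. With array weights they were 446, then 577, 551, 570 and 81, and 84, with 993 among clones. Without dim rows, which leaves fewer tests, they were 270 for all clones, 48 for clone 6 and 85 against B6 Blu ES. With all rows of the table, which adds the rows taken as controls, they were 22, then 22, 462, 186 and 3, and 10, with 927 among clones. With the compared lines alone, which leaves fewer arrays to estimate the spread, they were 7, 32, 59 and 2 for clones 1, 2, 5 and 6, 6 against B6 Blu ES and 784 among clones. Without clone 2, 134 rows differed among clones.

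Leaving out 1 array at a time gave 4052 to 6063 rows in clones minus MEF, 6 to 183 in clones minus MPSVII ES, 3198 to 4659 in MPSVII ES minus MEF, 6 to 49 in MPSVII ES minus B6 Blu ES, 7 to 199, 32 to 1005, 13 to 316 and 2 to 11 in clones 1, 2, 5 and 6, 487 to 1352 among clones, and 35 to 45 gene list calls, with 35 without MPSVII ES replicate 2. The lowest values in clones minus MPSVII ES (6), in MPSVII ES minus B6 Blu ES (6) and in clones 1 and 2 (7 and 32) came without MPSVII ES replicate 1, that of clone 1 also without its replicate 2, that of clone 5 (13) without its replicate 2 and that among clones (487) without clone 2 replicate 2. For the mean of all clones, the median of MEF-high rows lay between -0.1014 and -0.0314 and that of ES-high rows between -0.1345 and -0.0090.

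Of 44 gene list calls in 96 tests, 0 passed camera with an estimated correlation (17 at an unadjusted p under 0.05), 27 passed fry, 44 the mean of rows per gene, 40 quantile normalization, 41 median centring, 44 the trended prior, 39 the intensity-dependent normalization, 38 of 41 without dim rows and 32 of 32 with the replicate block, and 0 turned direction in these. Among named genes, Dnmt3a in clones minus MEF, -0.62 in the deposited values, turned to 0.0534 after quantile normalization (adjusted p = 0.788). Leaving out 1 array kept 2956 gene results on their side of the threshold, ended 337 and added 7, and the replicate block ended 19 and kept 222. Signal near the background limits the dim genes, since a change there is compressed.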

Other observations

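None of the tests in these paragraphs was chosen after its result was seen. Genes of other cell types and of imprinting were set between the clones and MEF. Of 32 Hox genes, which set position along the body axis, 9 fell in the clones and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.112; fry adjusted p = 0.000604), led by Hoxc8 at -3.31, Hoxc6 at -2.35 and Hoxa5 at -2.25 (-1.41 without MEF replicate 1 and -3.10 without MEF replicate 2). Of 24 imprinted genes outside the Dlk1 to Dio3 region 3 rose and 12 fell, with the same counts adjusted over the list alone (median -0.52, 0.05 after quantile normalization; camera adjusted p = 0.229; fry adjusted p = 0.006). The growth-related H19 RNA stood at -4.02, Igf2r, the receptor that clears insulin-like growth factor, at -3.19, and the amino acid transporter Slc38a4 at 3.23. The 3 genes Dlk1, Rtl1 and Dio3 had 0 called (camera adjusted p = 0.863).

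Of 20 interferon response genes 7 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.16; fry adjusted p = 0.00106; median -0.23, 0.03 after median centring), among them B2m, the light chain of class I molecules, at -3.35, Ifit2 at -2.29 and the proteasome subunit Psmb8 at -2.18. In MPSVII ES minus MEF 9 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.0329; adjusted p = 0.526 with an estimated correlation, and not passing without MPSVII ES replicate 2, median -0.67). The blood and macrophage markers, high on the same MEF arrays, had a median of -3.89 in the clones minus MEF.

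None of the lineage lists passed camera between the clones and MEF, and, apart from mesoderm, their member counts were the same adjusted over the list alone. By fry the endoderm list passed (adjusted p = 0.00149), and the other lists of this paragraph did not. Of 18 endoderm genes 1 rose and 5 fell, with Dab2 at -5.92 and Cxcr4 at -2.40 (camera adjusted p = 0.585; median -0.13, 0.10 after quantile normalization). Of 16 ectoderm and neural genes 3 fell, including Ncam1 at -1.97 and the intermediate filament gene Nes at -1.64 (camera adjusted p = 0.575; 4 higher and 3 lower after quantile normalization). Of 21 mesoderm genes 2 fell over all rows and 0 adjusted over the list alone (camera adjusted p = 0.4). Of 11 trophoblast genes 2 fell (camera adjusted p = 0.766). Of 14 primed epiblast genes 2 rose and 2 fell (camera adjusted p = 0.179), with the methyltransferase gene Dnmt3b higher by 2.60 and Otx2 by 0.82 (0.61 and not passing without MEF replicate 1). Of 14 endothelial genes 2 rose and 3 fell (camera adjusted p = 0.297; 5 higher and 2 lower after quantile normalization), with Pecam1 at 1.85 and Emcn at -1.34 (-0.65 and not passing without MEF replicate 1). Of 11 muscle genes 2 rose and 1 fell, the myosin light chain gene Mylpf by 3.74 among them (camera adjusted p = 0.107). The 2 genes of the early embryonic list, of cells like those of the embryo after its first division, had 0 called (camera adjusted p = 0.774), and the 2 sex-linked genes had 0 called between the clones and MEF (camera adjusted p = 0.915).

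Between the clones and MPSVII ES single members of the lineage lists passed the test while their lists did not. Map2, a neuronal microtubule protein gene, was higher by 1.04 ± 0.20, and Bmp4, a signalling factor of mesoderm, stood at -1.37 ± 0.27, the endothelial adhesion gene Pecam1 at -1.44 ± 0.27, Mylpf at -1.28 ± 0.24 and Laptm5 lower as well (adjusted p = 0.0156). Leaving out 1 array ended these calls in 8, 10, 7, 7 and 2 of 12 fits. Camera gave adjusted p = 0.169, 0.571, 0.567, 0.575 and 0.419 for their lists.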
